A study of Macaca mulatta with 81 samples.

How the data were processed

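Rhesus macaque T cells sorted on CD3 from blood were measured on 81 Affymetrix expression arrays from 50 animals, of which 11 gave both a healthy and a transplant array. Labelled RNA was made by the 3' IVT Plus protocol, and each array holds 52865 probe sets. Groups, days and the 4 batches were taken from the labels, which do not spell out the abbreviated prophylaxis names.

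The deposited values are log2 probe set signals that the submitters made with RMA in affy, with no versions given. Values ran from 1.52 to 16.67, above the ceiling of 16 of the scanner scale, and the medians of the arrays from 5.12 to 5.30. Among the healthy controls an F test between batches gave a p above 0.95 for 61.02% of probe sets, where 5% would be expected, so the deposited values carry a batch adjustment made before deposit whose method is not stated. The control arrays of a batch therefore say little about its size, and the spread of the values may be understated.

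A gene table named 25330 of the probe sets, 24969 with 1 gene and 361 with several. The 27535 others have no gene name here, so their genes could not be tested by name, and some genes are not reported here. Probe sets with 1 gene were kept, and of several for a gene the one with the highest mean was used, giving 14132 genes. Those above the 40th percentile of all values (4.65) in at least 2 arrays, 11806, were tested. For the test limma 3.58.1 in R 4.3.3 was used with statmod 1.5.0: lmFit on all 81 arrays with group and batch as terms, 62 residual degrees of freedom, and eBayes with a trend. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Adjusted p and SE are from this fit, 2-sided, and differences between effects, a test added after the data were seen, were tested as contrasts of it.

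There were 33 comparisons: each of the 15 transplant groups against healthy controls, no prophylaxis against autologous recipients, each prophylaxis against none, added Siro, the CD28 agents against each other, day 14 against autologous recipients, and later against earlier samples. Results of comparisons that share a reference (34 healthy control, 4 NoRx.F or 3 Auto.D14 arrays) are not independent. The 28 gene lists cover T cell functions, metabolism and markers of other blood cells. They were tested with camera at a preset correlation of 0.01 and adjusted over all 924 tests. Of these, 213 passed, and 2 passed with an estimated correlation as well, both of the Th17 and Tc17 list (Bela.Siro.F against healthy controls and against Bela.F). The members of a list are also given with p adjusted over the list alone. A list score is the mean of the members of a list in an array, relative to the healthy controls.

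The genes named were set by a rule. In the main comparisons these are the 5 largest rises and falls among genes past the threshold with every array of the group on the same side of the reference mean after the batch effect was removed, up to 4 members of each list with the smallest adjusted p, and a fixed set that includes MKI67, AURKA, GZMB, IFNG, TBX21, FOXP3, CTLA4, CD28, CCR7, IL17A and IL23R. In other comparisons these are the 3 largest and the list members. Genes with LOC symbols were passed over. Of the lists past the threshold, their members and the fixed set only a part is printed, and that part was chosen after the values were seen. Design, comparisons, lists, named gene rule and alternatives were fixed before the data were examined, apart from those named as later additions.

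Spike-in probe sets of added control transcripts were above the healthy control maximum of 11.27 in 8 arrays: all 4 of FR104.Siro.D14, and 1 each of Auto.D14, FR104.D14, FR104.Siro.F and Bela.Siro.F. Whether arrays of 1 animal resemble each other was checked after group means were removed. In the comparisons over time the correlation of such pairs was 0.21 to 0.57, in 3 of 3 or 4 of 4 pairs the highest with the own animal, and against their own healthy array -0.19 to 0.18 in allogeneic and 0.18 to 0.33 in autologous recipients (3 of 6 of the latter the highest with the own animal). The animal was an alternative, as a random block (correlation 0.194), and not part of the fit.

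The test was tried on simulated data with group sizes of 4 comparisons. Of 50 genes planted at a log2 change of 1, 46, 40, 44 and 40 were found in the designs of NoRx.F against healthy controls and Auto.D14, FR104.Siro.F against FR104.F and FR104.F against FR104.D14. Of the calls, 7 of 200, 6 of 166, 6 of 177 and 11 of 177 were false, the last over 5%. Rates in the real data may differ. Alternatives were a fit without batch, the animal block, no filter, the mean of the probe sets of a gene, renewed quantile normalization, only the groups compared with healthy controls, each batch alone, only day 14 arrays in FR104.Siro.D14, and each transplant array left out. Leaving an array out of a group of 2 leaves 1 array, assumed to vary like the other groups. Added after the data were seen were the spike-in signal as a covariate, the omission of the 8 arrays where it was high, the actin 3' minus 5' signal (log2, a measure of RNA quality) as a covariate, splits that part the 2 arrays of every animal, and for the differences between effects the animal block and the omission of each array. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.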

Results

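T cells carrying CD3 were sorted from the blood of rhesus macaques and profiled on expression arrays, 81 in all. Of these, 34 came from healthy controls that had not been transplanted (Healthy.Control) and 47 from 27 animals after hematopoietic cell transplant. The allogeneic groups differed in the prophylaxis against graft-versus-host disease. NoRx received none (NoRx.F, n = 4). Siro is taken here to be sirolimus, an inhibitor of mTOR (Siro.F, n = 4). Tac.Mtx is taken to be the calcineurin inhibitor tacrolimus with methotrexate (D14, n = 3; D30, n = 2; F, n = 3). Bela is taken to be belatacept, a CTLA4 fusion protein that covers the ligands of CD28 (F, n = 3), and Bela.Siro its combination with Siro (D14, n = 3; D30, n = 3; F, n = 2). FR104 is an antibody fragment that blocks CD28 itself (D14, n = 3; F, n = 3), and FR104.Siro its combination with Siro (D14, n = 4; F, n = 4). Autologous recipients (Auto.D14, n = 3; Auto.D36, n = 3) went through the procedure without a foreign graft. D14, D30 and D36 are nominal days after transplant, and F is the final sample, for which no day is given. The FR104.Siro.D14 arrays were from days 14, 14, 22 and 34. All values are log2, and changes are log2 differences from the limma fit with ± SE. The small number of arrays per group limits the precision.

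The first question was how T cells changed after an allogeneic transplant with no prophylaxis. Cell cycle genes rose in NoRx.F: CCNB2, a mitotic cyclin, was 27.2-fold higher than in healthy controls (log2 change 4.77 ± 0.40, adjusted p 3.77e-15; mean 10.46 ± 0.66 SD, n = 4, against 5.72 ± 0.48, n = 34). MKI67, a marker of dividing cells, rose by 3.41 ± 0.31, and TYMS, which makes thymidylate for DNA synthesis, by 4.00 ± 0.46. Single genes of effector and inhibited T cells rose as well: LAG3, an inhibitory receptor, by 3.82 ± 0.31, GZMB, a killing enzyme, by 1.64 ± 0.41, GNLY, a pore-forming granule protein, by 2.06 ± 0.40, and CXCR3, a receptor for homing to inflamed tissue, by 1.49 ± 0.22. CTLA4, which competes with CD28, rose by 1.44 ± 0.34, and ENTPD1, an ATP-degrading enzyme of regulatory and exhausted T cells, by 2.62 ± 0.30. The cytotoxic effector, inhibitory receptor and regulatory T cell lists did not pass as wholes: 8 of 16, 6 of 12 and 6 of 12 rose, 8, 6 and 7 adjusted over the list alone, and 2 inhibitory receptors fell (adjusted p 0.115, 0.0892 and 0.0515, with an estimated correlation 0.708, 0.426 and 0.302). Genes of resting T cells fell: TCF7, a transcription factor of naive and memory cells, by 1.64 ± 0.18, CCR7, the lymph node homing receptor, by 1.31 ± 0.36, and FOXP1, which maintains quiescence, by 1.26 ± 0.13.

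Other leading genes in NoRx.F against healthy controls were IFI27, induced by type I interferon (3.87 ± 0.49), and PTPN13 (-3.26 ± 0.35). SOX4 (-3.10 ± 0.80), METTL14 (-3.05 ± 0.75), TAGAP (-2.95 ± 0.24), and ZBTB20 (-2.75 ± 0.21) fell as well. Values for IFNG, TBX21 and FOXP3 were 0.96 ± 0.49, 0.30 ± 0.41 and -0.04 ± 0.15, with adjusted p of 0.123, 0.614 and 0.875. In all, 4181 of 11806 genes passed the threshold, 2361 higher and 1820 lower, and 398 and 374 of them by at least 2-fold. Of the 18 cell cycle genes tested, 17 rose, and 17 rose when adjusted over the list alone (median 2.27, adjusted p 4.07e-15, 0.156 with an estimated correlation). Glycolysis had 11 of 13 genes higher and 11 adjusted over the list alone (median 0.79, adjusted p 3.23e-06, 0.195 with an estimated correlation), led by LDHA, which turns pyruvate into lactate (1.32 ± 0.10). Oxidative phosphorylation had 8 of 9 genes higher, 8 adjusted over the list alone (median 0.65, adjusted p 2.34e-05, 0.232 with an estimated correlation). Type I interferon response genes rose in 11 and fell in 1 of 17 cases, the same counts adjusted over the list alone (median 1.01, adjusted p 0.00311, 0.461 with an estimated correlation). Among 10 naive and quiescent T cell genes, 5 fell, and 6 when adjusted over the list alone (median -0.68, adjusted p 0.00111, 0.302 with an estimated correlation).

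S100A8 and S100A9, calcium-binding proteins abundant in monocytes and neutrophils, were 24.9-fold and 30.0-fold higher in NoRx.F than in healthy controls (4.64 ± 0.79 and 4.91 ± 0.83), with a wide spread between the 4 animals (SD 2.08 and 2.13). Of 12 monocyte and myeloid markers, 5 rose, 6 rose and 1 fell when adjusted over the list alone, and the list as a whole did not pass (median 0.22, mean 1.13, adjusted p 0.366, 0.812 with an estimated correlation). CD8A and CD8B, the CD8 coreceptor, rose by 0.75 ± 0.16 and 1.13 ± 0.27, while KLRF1, an NK cell receptor, fell by 2.72 ± 0.72. Batch 1 alone, with 3 NoRx.F arrays, gave 3566 genes.

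**Figure D1:**
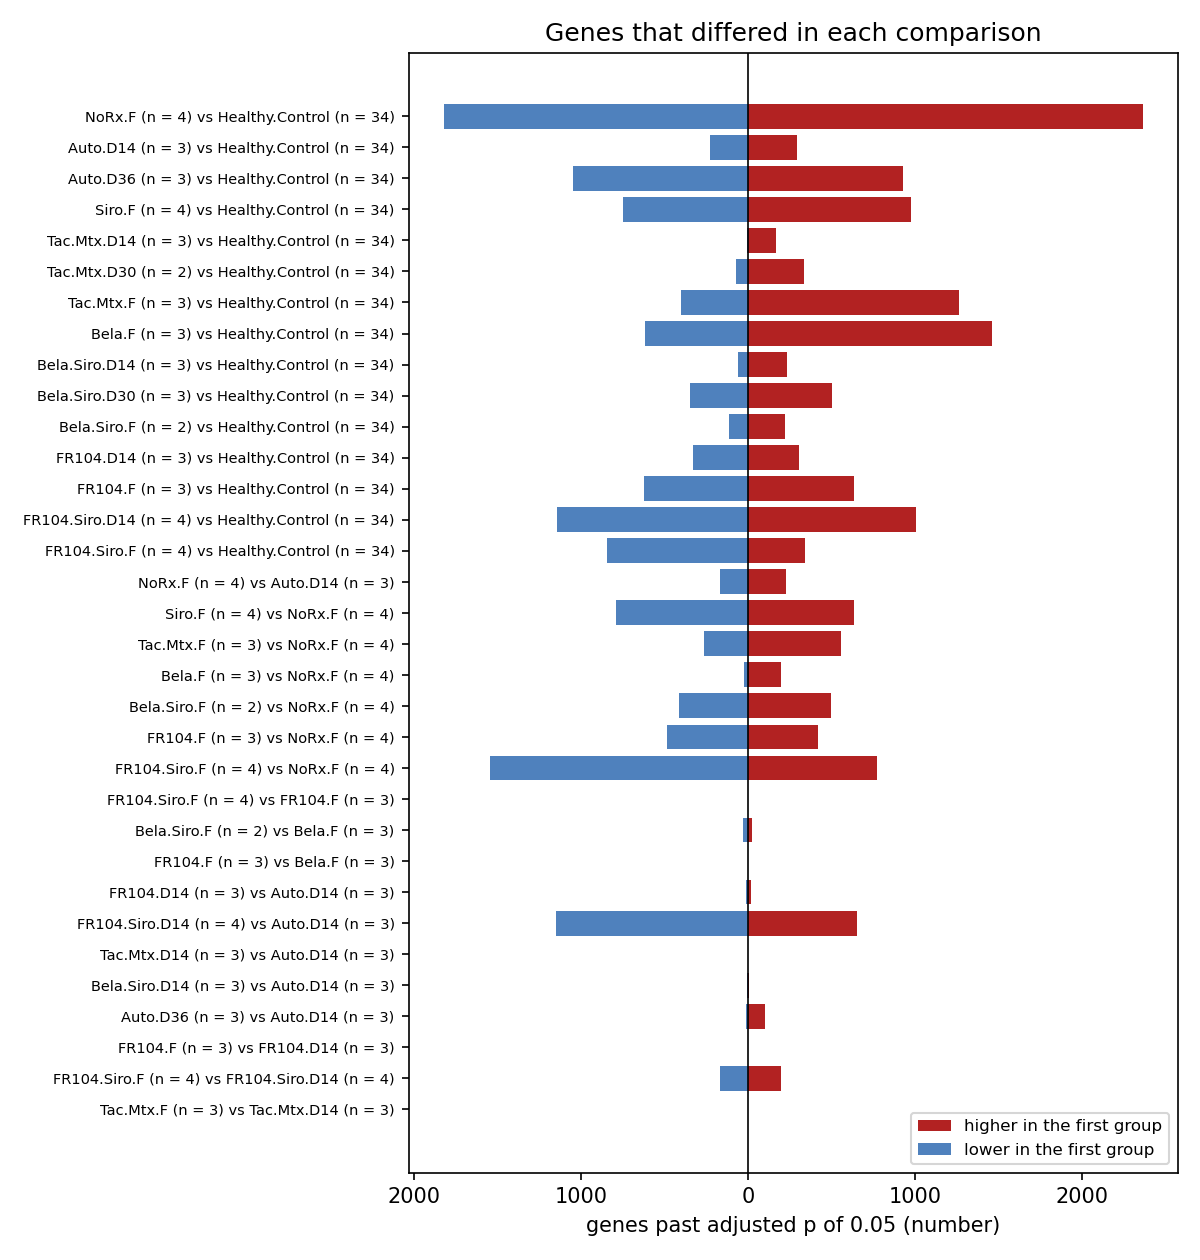
Genes past an adjusted p of 0.05 in each of the 33 comparisons, as numbers on the horizontal axis, with genes higher in the first group to the right and lower to the left of 0. NoRx.F against healthy controls had the most, 2361 higher and 1820 lower, and the comparison of FR104.F with FR104.D14 had 0.

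Autologous recipients at day 14 were used to ask which changes came with the procedure itself. Relative to healthy controls, IFI27 rose by 3.59 ± 0.59, LAG3 by 2.56 ± 0.37, CD70 by 2.36 ± 0.37, MB by 3.05 ± 0.45, and SERPINE2 by 2.34 ± 0.56 (n = 3 against 34). SOX4 fell by 3.55 ± 0.96, and so did MAML3 by 2.33 ± 0.43, AUTS2 by 2.02 ± 0.43, IRS2 by 1.87 ± 0.39, and SWAP70 by 1.83 ± 0.47. MKI67 rose by 1.61 ± 0.37, whereas GZMB (1.00 ± 0.49) and CCR7 (-0.78 ± 0.43) did not pass, with adjusted p of 0.26 and 0.332. Cell cycle genes were higher in 12 of 18 cases and 16 adjusted over the list alone (median 1.06, adjusted p 8.7e-13, 0.215 with an estimated correlation). Type I interferon response genes were higher in 5 of 17, with 5 higher and 1 lower adjusted over the list alone (median 0.60, adjusted p 1.78e-05, 0.302 with an estimated correlation). The comparison called 519 genes, 292 higher and 227 lower, but 21 without Auto.D14 replicate 202, an array whose spike-in signal of 12.14 was above the 11.27 reached by healthy controls. It called 798 genes with the animal as a random block and 90 within batch 4 alone.

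NoRx.F, of unstated day, was set against autologous recipients at day 14, which mixes graft and time. Genes of cell division were higher: CCNB2 rose by 2.88 ± 0.63, CDKN3 by 2.12 ± 0.49, MCM4, of the DNA replication helicase, by 2.00 ± 0.41, CCNB1, another mitotic cyclin, by 1.83 ± 0.40, and MKI67 by 1.80 ± 0.49 (n = 4 against 3). FES rose by 1.99 ± 0.35, HAVCR2, the inhibitory receptor TIM-3, by 1.33 ± 0.34, and the glycolytic enzymes ENO1 and LDHA by 0.88 ± 0.12 and 0.78 ± 0.15. METTL14 fell by 3.91 ± 1.17, TAGAP by 2.29 ± 0.37, PTPN13 by 2.28 ± 0.55, PCMTD1 by 1.89 ± 0.27, ARRDC3 by 1.79 ± 0.38, and TCF7 by 0.98 ± 0.28. GZMB, TBX21 and IFNG gave 0.64 ± 0.64, -0.32 ± 0.64 and -0.60 ± 0.76, with adjusted p of 0.693, 0.87 and 0.771. Cell cycle genes rose in 6 of 18 cases and 12 adjusted over the list alone (median 1.28, adjusted p 6.45e-09, 0.302 with an estimated correlation), glycolysis genes in 2 of 13 and 9 adjusted over the list alone (median 0.57, adjusted p 8.07e-08, 0.156 with an estimated correlation). Plasma cell markers rose in 1 of 4 and 3 adjusted over the list alone (median 0.705, adjusted p 0.00873, 0.236 with an estimated correlation). In all, 393 genes passed, 224 higher and 169 lower, and 696 with the animal as a random block. The groups shared no batch, and the count was 239, 199, 175 and 199 without Auto.D14 replicates 201 and 200 and NoRx.F replicates 50 and 52, and 790 without NoRx.F replicate 53, the only NoRx.F array of batch 2.

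Final, undated samples of each prophylaxis were set against NoRx.F, in which PTPN13 had itself fallen, so a rise can come from NoRx.F. Under FR104, genes of resting T cells rose and killing genes fell (n = 3 against 4). SOCS2 and CISH, feedback inhibitors of cytokine signalling, rose by 3.50 ± 0.82 and 2.73 ± 0.49, AATK by 2.63 ± 0.40, LPAR6 by 2.57 ± 0.47, and CA6 by 2.49 ± 0.47. CCR7 rose by 1.88 ± 0.56, TCF7 by 1.51 ± 0.28, and MYC, a driver of growth, by 1.97 ± 0.45. The granzymes GZMH and GZMB fell by 3.18 ± 0.89 and 2.38 ± 0.64, BDKRB1 by 2.33 ± 0.59, CCNB2 by 2.32 ± 0.63, SLAMF7, a receptor of cytotoxic cells, by 2.25 ± 0.67, and CXCR3 by 1.54 ± 0.34. MKI67 was at -1.32 ± 0.49 with an adjusted p of 0.0798. Naive and quiescent T cell genes rose in 5 of 10 cases and 7 adjusted over the list alone (median 0.85, adjusted p 3.12e-06, 0.156 with an estimated correlation). Cytotoxic effector genes fell in 5 of 16 and 7 adjusted over the list alone (median -1.43, adjusted p 0.00895, 0.544 with an estimated correlation), and cell cycle genes in 3 of 18 and 6 adjusted over the list alone (median -0.80, adjusted p 0.005, 0.626 with an estimated correlation). Without FR104.F replicate 22 the cytotoxic list gave an adjusted p of 0.211, at a median of -0.88, and without FR104.F replicate 23 the cell cycle list 0.0501 at -0.68. Plasma cell markers fell in 1 of 4 and 2 adjusted over the list alone (median -0.67, adjusted p 0.0342, 0.302 with an estimated correlation; adjusted p 0.0854 without FR104.F replicate 22). The 906 genes, 418 higher and 488 lower, became 294 and 504 without FR104.F replicates 23 and 24, and 541 and 528 without NoRx.F replicates 50 and 52. The groups shared no batch, and the actin 3' minus 5' signal was 0.095 to 0.425 in FR104.F and 0.61 to 1.14 in NoRx.F. With it as a covariate 906 genes passed.

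More genes passed against NoRx.F in FR104.Siro.F than in the other 5 prophylaxis groups, mostly smaller (n = 4 against 4). SOCS2 rose by 4.81 ± 0.77, PTPN13 by 3.73 ± 0.52, DACT1 by 3.44 ± 0.59, AATK by 3.21 ± 0.38, CHN1 by 2.95 ± 0.70, and CCR7 by 1.80 ± 0.53. FGFBP2, secreted by cytotoxic lymphocytes, fell by 4.55 ± 0.87, GZMH fell by 4.02 ± 0.84, SLAMF7 by 3.86 ± 0.64, CCNB2 by 3.48 ± 0.60, GZMB by 3.01 ± 0.61, MKI67 by 2.41 ± 0.46, and TBX21, the transcription factor of Th1 and effector CD8 cells, by 2.26 ± 0.61. CD8A fell by 0.70 ± 0.24 and CD4 rose by 0.84 ± 0.27. FOXP3, the factor of regulatory T cells, and CTLA4 were at 0.18 ± 0.22 and -0.72 ± 0.50, with adjusted p of 0.642 and 0.34. Cytotoxic effector genes fell in 8 of 16 cases, 8 adjusted over the list alone (median -2.00, adjusted p 2.47e-05, 0.321 with an estimated correlation). Cell cycle genes fell in 12 of 18 and 14 adjusted over the list alone (median -1.35, adjusted p 2.29e-07, 0.342 with an estimated correlation), and glycolysis genes in 7 of 13 and 10 adjusted over the list alone (median -0.58, adjusted p 7.5e-05, 0.272 with an estimated correlation). Naive and quiescent T cell genes rose in 7 of 10 cases and 8 adjusted over the list alone (median 1.13, adjusted p 3.67e-06, 0.156 with an estimated correlation). Of 2319 genes, 773 were higher and 1546 lower, 292 and 308 of them by at least 2-fold, and without 1 array the count was 1862 to 2487. The groups shared no batch.

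Under Bela alone few genes differed from NoRx.F (n = 3 against 4). CA6 rose by 2.49 ± 0.45, LCN2 by 2.28 ± 0.49, FAM241A by 2.14 ± 0.37, GCA by 2.14 ± 0.48, DACT1 by 2.07 ± 0.59 and TCF7 by 1.30 ± 0.26. SLC27A2 fell by 1.61 ± 0.37, TSFM by 0.94 ± 0.26, SLC16A3 by 0.81 ± 0.22, ATP5IF1 by 0.80 ± 0.15, and CARHSP1 by 0.79 ± 0.23. GZMB and MKI67 were at -0.23 ± 0.61 and -1.0 ± 0.46, with adjusted p of 0.931 and 0.309. Naive and quiescent T cell genes rose in 2 of 10 cases, 2 adjusted over the list alone (median 0.39, adjusted p 0.00309, 0.35 with an estimated correlation). Cell cycle and oxidative phosphorylation genes moved down as lists, with 0 of 18 and 0 of 9 called, also adjusted over the list alone (median -0.43 and -0.33, adjusted p 0.0213 and 0.00607, with an estimated correlation 0.683 and 0.404). Without Bela.F replicate 57 they were at -0.20 and -0.23, with adjusted p of 0.584 and 0.0881. The cell cycle list also missed the threshold without NoRx.F replicate 50 or 52. Of 220 genes, 197 were higher and 23 lower. The count was 86 without Bela.F replicate 57, 110 and 116 without NoRx.F replicates 51 and 52 and 454 without NoRx.F replicate 53, and the groups shared no batch.

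With Bela and Siro together, genes of the interleukin 17 program rose against NoRx.F (n = 2 against 4). The cytokines IL17A, IL22 and IL26 rose by 2.24 ± 0.24, 1.71 ± 0.23 and 3.23 ± 0.58, and RORA, a transcription factor of the program, by 1.46 ± 0.42. PCDH8 rose by 4.46 ± 0.37, SOCS2 by 4.20 ± 0.85, CHN1 by 3.55 ± 0.77 and PTPN13 by 3.44 ± 0.57. FGFBP2 fell by 4.66 ± 0.96, CCNB2 by 3.10 ± 0.66, LAG3 by 2.97 ± 0.51, SLAMF7 by 2.85 ± 0.70, GZMB by 2.57 ± 0.67 and MKI67 by 2.44 ± 0.51, and CD8A and CD8B fell by 1.11 ± 0.26 and 1.5 ± 0.44. Th17 and Tc17 genes rose in 4 of 14 cases, with 6 higher and 1 lower adjusted over the list alone (median 0.66, adjusted p 5.71e-05, 0.156 with an estimated correlation). Cell cycle genes fell in 11 of 18 and 14 adjusted over the list alone (median -1.58, adjusted p 7.16e-11, 0.249 with an estimated correlation), and cytotoxic effector genes in 7 of 16 and 8 adjusted over the list alone (median -1.76, adjusted p 3.07e-05, 0.327 with an estimated correlation). Immediate early stress response genes rose in 2 of 7 and 5 adjusted over the list alone (median 1.00, adjusted p 0.00272, 0.302 with an estimated correlation; 0.73, adjusted p 0.0802, without Bela.Siro.F replicate 42). Of 915 genes, 498 were higher and 417 lower, and the count was 316 without Bela.Siro.F replicate 42, which leaves 1 array assumed to vary like the other groups. Of the genes named, CCNB2, GZMB, MKI67 and SLAMF7 then missed the threshold and IL22 was at 0.97, and without replicate 38 IL26 (1.60), RORA (1.04), CHN1 and CD8B missed it. The groups shared no batch.

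Under Siro alone, proliferation and interferon genes were lower than in NoRx.F (n = 4 against 4). CCNB2 fell by 2.37 ± 0.49, CDKN3 by 1.98 ± 0.38, H1-3, a histone, by 1.87 ± 0.53, MKI67 by 1.74 ± 0.38, FGFBP2 by 2.57 ± 0.71 and IFI27 by 2.48 ± 0.60. PTPN13 rose by 3.27 ± 0.42, CISH by 2.53 ± 0.38, AATK by 2.49 ± 0.31, SOCS2 by 2.34 ± 0.63, SUN1 by 2.01 ± 0.23, and TCF7 by 1.40 ± 0.22. GZMB was at -1.26 ± 0.50 and CCR7 at 1.07 ± 0.43, with adjusted p of 0.0881 and 0.0967. Cell cycle genes fell in 11 of 18 cases, 11 adjusted over the list alone (median -0.94, adjusted p 3.17e-07, 0.344 with an estimated correlation), and oxidative phosphorylation genes in 6 of 9 and 7 adjusted over the list alone (median -0.57, adjusted p 1.17e-06, 0.156 with an estimated correlation). Type I interferon response genes fell in 6 of 17 cases, with 8 lower and 1 higher adjusted over the list alone (median -0.72, adjusted p 0.00607, 0.494 with an estimated correlation; -0.45, adjusted p 0.0609, without NoRx.F replicate 52). Immediate early stress response genes rose in 2 of 7 and 5 adjusted over the list alone (median 1.00, adjusted p 0.00875, 0.359 with an estimated correlation; 0.86, adjusted p 0.0683, without Siro.F replicate 18). Of 1425 genes, 636 were higher and 789 lower, and batch 1 alone gave 1246. Without Siro.F replicates 16 and 17 the count was 845 and 937, and without NoRx.F replicates 50 and 52 it was 871 and 924.

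Under tacrolimus and methotrexate, early response genes rose over NoRx.F (n = 3 against 4). FOS and JUNB, AP-1 transcription factors, rose by 5.07 ± 1.41 and 2.47 ± 0.45, DUSP1, a phosphatase that limits MAP kinases, by 3.20 ± 0.83, RGS1 by 2.95 ± 0.72, PTPN13 by 3.42 ± 0.52, and ADAM12 by 2.85 ± 0.68. CCNB2 fell by 3.00 ± 0.59, ACKR1 by 2.60 ± 0.50, SERPINE2 by 2.35 ± 0.70, LAG3 by 2.12 ± 0.46, TYMS by 2.07 ± 0.68 and MKI67 by 1.94 ± 0.46. IL17A rose by 0.99 ± 0.22, and GZMB was at -1.20 ± 0.61 with an adjusted p of 0.239. Immediate early stress response genes rose in 5 of 7 cases, 5 adjusted over the list alone (median 1.04, adjusted p 0.000716, 0.266 with an estimated correlation). Cell cycle genes fell in 13 of 18, 13 adjusted over the list alone (median -1.30, adjusted p 1.03e-10, 0.256 with an estimated correlation). Plasma cell markers fell in 1 of 4, 1 adjusted over the list alone (median -0.37, adjusted p 0.0258, 0.302 with an estimated correlation; adjusted p 0.0657 without Tac.Mtx.F replicate 21). Of 820 genes, 555 were higher and 265 lower, and 432 passed without Tac.Mtx.F replicate 19. The groups shared no batch.

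**Figure D2:**
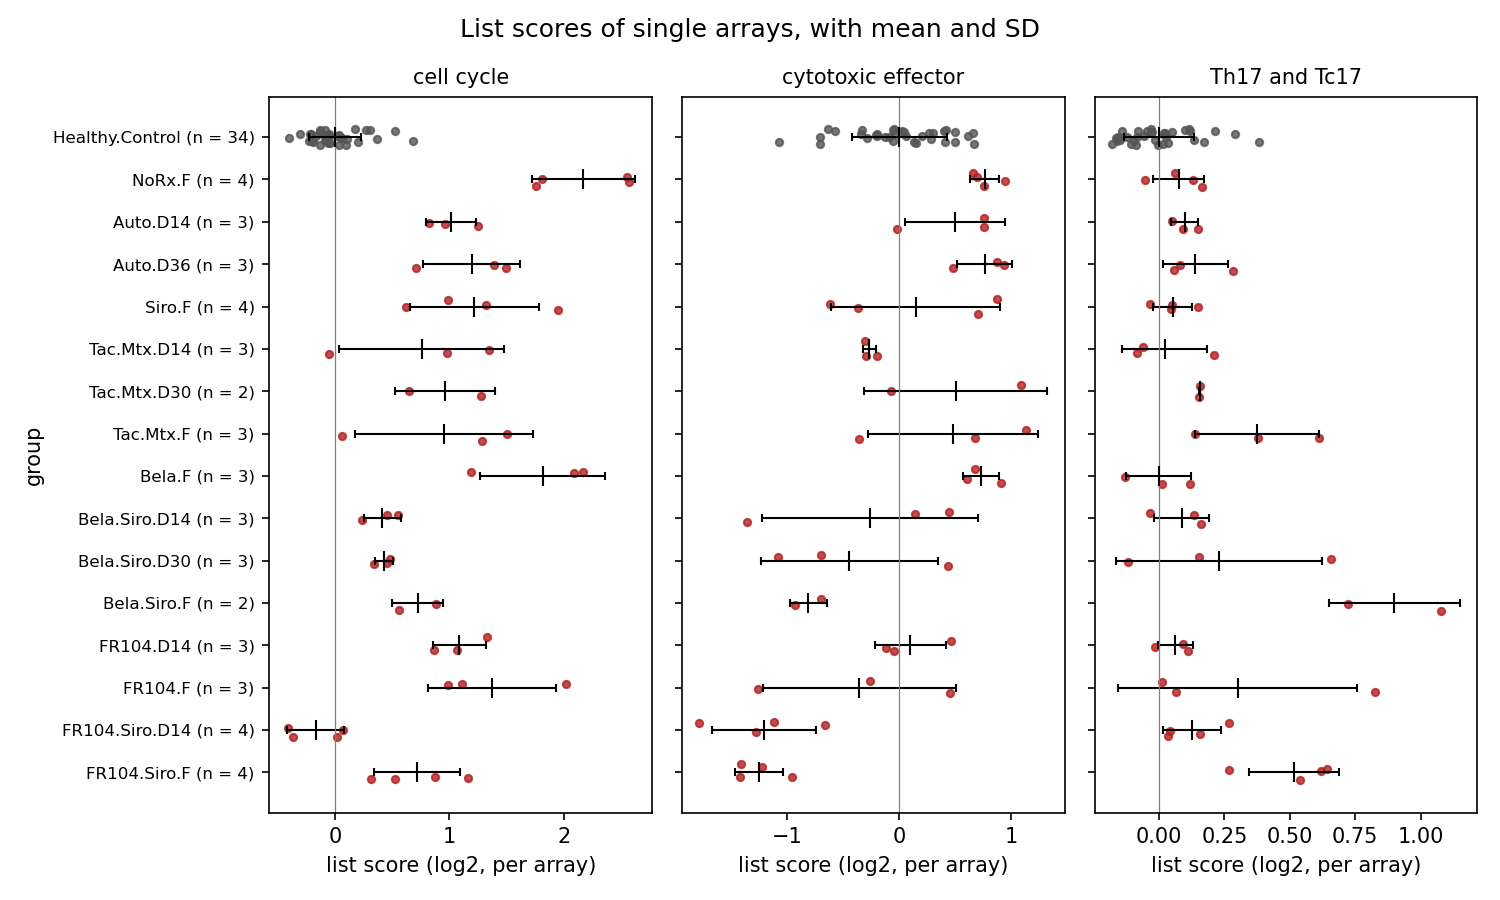
Scores of 3 gene lists in single arrays, in log2 units relative to healthy controls on the horizontal axes, by group, with black marks for the mean and bars for the SD. The cell cycle scores of the 4 NoRx.F arrays averaged 2.17, and the Th17 and Tc17 scores of the 2 Bela.Siro.F arrays averaged 0.90.

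The addition of Siro to FR104 was tested within batch 4. PCDH8 (probe set MmuSTS.3573.1.S1_at) rose by 2.12 ± 0.29 in all 4 arrays (adjusted p 5e-06, n = 4 against 3), and it was the only gene past the threshold, beside 876 at an unadjusted p under 0.05. Within batch 4 alone limma called 0 genes, with 776 at an unadjusted p under 0.05. No cell cycle gene of 18 passed over all genes, while 7 fell when adjusted over the list alone (median -0.75, adjusted p 5.26e-09, 0.302 with an estimated correlation), with MKI67 at -1.09 ± 0.40 and an adjusted p of 0.556. Cytotoxic effector genes fell in 2 of 16 cases adjusted over the list alone and in 0 over all genes (median -0.71, adjusted p 3.44e-05, 0.333 with an estimated correlation; -0.275, adjusted p 0.079, without FR104.F replicate 24), with GZMB at -0.64 ± 0.53 (0.024 without FR104.F replicate 24) and TBX21 at -1.24 ± 0.53 (adjusted p 0.833 and 0.62). Erythroid markers moved down with 0 of 6 called, also adjusted over the list alone (median -0.97, adjusted p 0.00395, 0.433 with an estimated correlation). Without FR104.F replicate 24 they were at -0.16 (adjusted p 0.755). The count was 2 without FR104.F replicate 22 or 23 and 3 without FR104.Siro.F replicate 28 or 29.

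With Siro added to Bela, genes of the interleukin 17 program rose (n = 2 against 3, all in batch 3). IL17A rose by 2.11 ± 0.23, IL22 by 1.75 ± 0.22, IL26 by 3.21 ± 0.55, CCR6, the chemokine receptor of Th17 cells, by 1.61 ± 0.41, PCDH8 by 4.11 ± 0.35 and CHN1 by 3.61 ± 0.73. LAG3 fell by 2.86 ± 0.48, CCRL2 by 2.33 ± 0.53, SYTL3 by 2.17 ± 0.48, and HAVCR2 by 1.52 ± 0.34. Th17 and Tc17 genes rose in 4 of 14 cases and 8 adjusted over the list alone (median 0.83, adjusted p 3.34e-14, 0.00143 with an estimated correlation). Cell cycle genes fell in 3 of 18 and 12 adjusted over the list alone (median -1.11, adjusted p 1e-12, 0.215 with an estimated correlation), and cytotoxic effector genes in 1 of 16 and 9 adjusted over the list alone (median -1.77, adjusted p 9.99e-09, 0.195 with an estimated correlation). CD8A and CD8B were at -0.82 ± 0.25 and -0.72 ± 0.42 (adjusted p 0.118 and 0.665, CD8B 0.019 without Bela.Siro.F replicate 38), and the NK cell markers at a median of -0.67, with 0 of 9 called, also adjusted over the list alone (adjusted p 0.128, 0.591 with an estimated correlation). The 2 Bela.Siro.F arrays differed: without replicate 38 IL26 (1.58), CCR6 (0.81), CHN1, HAVCR2 and SYTL3 missed the threshold, and without replicate 42 CCRL2 and SYTL3 did and IL22 was at 1.01, while IL17A (2.01 and 2.215), PCDH8 and LAG3 passed both times. CCR6 also missed it with the animal as a random block. Of 54 genes, 22 were higher and 32 lower, and batch 3 alone gave 7. Of the genes named here, IL17A and PCDH8 passed in that fit, and IL22 (adjusted p 0.294), IL26 (0.321), CCR6 (0.368) and LAG3 (0.108), among others, did not. Without Bela.F replicates 47, 46 and 57 the count was 14, 27 and 179.

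The effect of Siro differed between the partners for 3 genes in a test of the difference itself. IL17A was -0.09 with FR104 and 2.11 with Bela (difference -2.20 ± 0.30, adjusted p 4.05e-06), IL22 was 0.43 and 1.75 (difference -1.32 ± 0.28, adjusted p 0.0487), and CRYBB1 was 0.14 and -1.34 (difference 1.47 ± 0.28, adjusted p 0.0112). At an unadjusted p under 0.05 there were 389. When each of the 12 arrays was left out in turn, IL17A passed every time, CRYBB1 missed the threshold without 5 and IL22 without 8 (-2.07 to -0.58). With the animal as a random block IL22 (-1.30, adjusted p 0.0713) and the inhibitory receptors below (0.0508) missed it as well. By lists, the difference was lower for immediate early stress response genes (median -0.89, adjusted p 9.61e-06, 0.0741 with an estimated correlation), erythroid markers (median -1.30, 0.000129, 0.406) and Th17 and Tc17 genes (median -0.495, 6.54e-08, 0.0192), and higher for inhibitory receptors (median 0.46, 0.044, 0.434). Without FR104.F replicate 24 the erythroid difference was at -0.50 (adjusted p 0.13). Over the 12 arrays left out the Th17 and Tc17 difference ran from -0.67 to -0.25, and the inhibitory receptors missed the threshold without 6. Between the single agents, FR104.F was lower than Bela.F for 4 genes (n = 3 against 3): SUCNR1 by -1.86 ± 0.39, CRYBB1 by -1.35 ± 0.23, EIF3I by -1.02 ± 0.22, and RBKS by -0.87 ± 0.18. At an unadjusted p under 0.05 there were 1087, and with the actin 3' minus 5' signal (0.095 to 0.425 in FR104.F, 0.87 to 1.36 in Bela.F) as a covariate 1 of the 4, CRYBB1, passed. GZMB was at -2.15 ± 0.67 with an adjusted p of 0.376. Cytotoxic effector genes fell in 2 of 16 cases adjusted over the list alone and in 0 over all genes (median -1.15, adjusted p 0.00271, 0.485 with an estimated correlation; -0.77, adjusted p 0.261, without FR104.F replicate 22). Plasma cell markers moved down, 1 of 4 adjusted over the list alone (median -0.64, adjusted p 0.0316, 0.302 with an estimated correlation). With 0 genes called either way, erythroid markers (6; median 0.87, adjusted p 0.00108, 0.377 with an estimated correlation), Th17 and Tc17 (14; 0.30, 0.00326, 0.302) and naive T cell genes (10; 0.37, 0.00228, 0.342) moved up. Without FR104.F replicate 24 the erythroid list was at 0.07 (adjusted p 0.321). Without FR104.F replicate 22 the Th17 and plasma cell lists were at medians of 0.033 and -0.594 (adjusted p 0.364 and 0.0902). The groups shared no batch, and the count was 16 without Bela.F replicate 57, 1 without FR104.F replicate 22, 23 or 24, and 0 by limma without Bela.F replicate 47, with 635 at an unadjusted p under 0.05.

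Near day 14 prophylaxed groups were set against autologous recipients, in which MB had itself risen over healthy controls. FR104.Siro.D14, the largest, gave the most genes (n = 4 against 3, batch 4). Killing genes were lower, with GZMH down by 3.18 ± 0.74. CCL3, an inflammatory chemokine, fell by 3.54 ± 0.81, IFNG by 2.60 ± 0.63, TBX21 by 2.27 ± 0.53, MKI67 by 2.08 ± 0.40 and MB by 3.07 ± 0.49. CCL23, a chemokine, rose by 3.32 ± 0.99, MYB, a factor of progenitor cells, by 2.68 ± 0.40, SOCS2 by 2.51 ± 0.68 and CCR7 by 1.82 ± 0.46. INSIG1 and IDI1, of cholesterol regulation and synthesis, fell by 1.10 ± 0.19 and 1.22 ± 0.24. Cytotoxic effector genes fell in 9 of 16 cases and 11 adjusted over the list alone (median -1.73, adjusted p 1.23e-06, 0.272 with an estimated correlation). Cell cycle genes fell in 12 of 18 and 14 adjusted over the list alone (median -1.27, adjusted p 2.13e-08, 0.302 with an estimated correlation), and cholesterol synthesis genes in 6 of 11, 6 adjusted over the list alone (median -0.57, adjusted p 0.000206, 0.156 with an estimated correlation). Of 1801 genes, 650 were higher and 1151 lower, 656 passed within batch 4 alone, 729 with the day 14 arrays alone, and 1188 with the spike-in signal, high in all 4 FR104.Siro.D14 arrays, as a covariate. Without Auto.D14 replicate 200 and FR104.Siro.D14 replicate 29 the count was 1071 and 1156.

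In FR104.D14 against Auto.D14, PLS3 rose by 2.87 ± 0.68, KIR3DH by 2.32 ± 0.46, PGAP1 by 2.13 ± 0.42, and MYC by 1.93 ± 0.40 (n = 3 against 3). BDKRB1 fell by 2.28 ± 0.53, TP63 by 1.98 ± 0.48, and TCHH by 1.70 ± 0.30. By lists with 0 genes called over all genes, 5 of 10 naive and quiescent T cell genes rose adjusted over the list alone (median 0.40, adjusted p 0.000353, 0.3 with an estimated correlation), and 5 of 7 immediate early stress response genes (median -0.73, 0.000392, 0.243) and 4 of 11 cholesterol synthesis genes fell (median -0.21, 0.0082, 0.302). The type I interferon list (0 of 17; median 0.40, adjusted p 0.0295, 0.598 with an estimated correlation) and the neutrophil and granule markers (3 of 8 adjusted over the list alone; median 0.48, 0.027, 0.442) moved up. The last 3 lists each missed the threshold without 1 of several arrays. Of 29 genes, 14 were higher and 15 lower, and batch 4 alone gave 17. The actin 3' minus 5' signal was 0.02 to 0.37 in FR104.D14 and 0.29 to 2.255 in Auto.D14, and with it as a covariate 22 genes passed. Without FR104.D14 replicates 22 and 24 and Auto.D14 replicate 202 the count was 14, 15 and 17, and without FR104.D14 replicate 23 limma called 0, with 916 at an unadjusted p under 0.05. Tac.Mtx.D14 differed from Auto.D14 in 2 genes, MYB (2.48 ± 0.50) and MB (-3.06 ± 0.61), beside 1020 at an unadjusted p under 0.05 (n = 3 against 3, no shared batch), and with the animal as a random block in 7. With 0 genes called over all genes, monocyte (1 of 12 adjusted over the list alone) and erythroid markers (5 of 6, and 1 lower) moved up (median 1.06 and 1.45, adjusted p 0.00181 and 0.00266, with an estimated correlation 0.415 and 0.412). Without Tac.Mtx.D14 replicate 21 the erythroid list was at 0.03 (adjusted p 0.97). Without Auto.D14 replicate 201 and Tac.Mtx.D14 replicates 20 and 19 the count was 26, 15 and 5, and without Auto.D14 replicates 200 and 202 and Tac.Mtx.D14 replicate 21 limma called 0, with 1238, 615 and 914 at an unadjusted p under 0.05. Bela.Siro.D14 differed in 11 genes (n = 3 against 3, no shared batch). MYB rose by 2.21 ± 0.50, FKBP4 by 1.20 ± 0.26, and UBALD2 by 1.12 ± 0.24, and MB, TP63 and TCHH fell by 2.91 ± 0.61, 2.5 ± 0.56 and 1.81 ± 0.35. Monocyte and myeloid markers rose in 4 of 12 cases adjusted over the list alone and 0 over all genes (median 1.05, adjusted p 0.00098, 0.392 with an estimated correlation). With the animal as a random block 19 genes passed, and 35 and 4 without Auto.D14 replicates 201 and 200. Without Auto.D14 replicate 202 and Bela.Siro.D14 replicates 42 and 49 limma called 0, with 959, 561 and 1443 at an unadjusted p under 0.05.

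Later samples were compared with earlier ones of the same group. In autologous recipients from day 14 to day 36, CX3CR1, the fractalkine receptor of cytotoxic and patrolling cells, rose by 2.72 ± 0.53, TST by 2.30 ± 0.43, STAT3 by 2.17 ± 0.49, and CD4 by 0.96 ± 0.25 (n = 3 against 3). CARMIL2 fell by 0.78 ± 0.20, MRPL52 by 0.76 ± 0.19, and CARM1 by 0.68 ± 0.15. The actin 3' minus 5' signal differed with time: it was -0.34 to -0.30 at day 36, below every healthy control (0.43 or more), and 0.29 to 2.255 at day 14. With it as a covariate, added after the data were seen, 1 gene passed, and none of the 7 named here did. Of 115 genes, 101 were higher and 14 lower, 339 passed with the animal as a random block, and 0 within batch 4 alone by limma, with 898 at an unadjusted p under 0.05. Without Auto.D14 replicates 201, 202 and 200 the count was 7, 8 and 565, and without Auto.D36 replicates 201, 200 and 202 it was 28, 42 and 61.

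From the early to the final sample under FR104.Siro, genes of dividing cells rose (n = 4 against 4): TOP2A, the topoisomerase of dividing cells, rose by 2.14 ± 0.52, CENPF by 1.58 ± 0.26, and MKI67 by 1.47 ± 0.37. ZBED2 rose by 2.62 ± 0.62, PLS3 by 2.34 ± 0.59 with its 1 other probe set lower, and MATN2 by 2.32 ± 0.55. The p53 targets PHLDA3, BAX and BBC3, which promote apoptosis, fell by 1.07 ± 0.15, 1.02 ± 0.19 and 0.93 ± 0.22. Cell cycle genes rose in 7 of 18 cases and 11 adjusted over the list alone (median 0.91, adjusted p 1.05e-09, 0.295 with an estimated correlation). Of 366 genes, 198 were higher and 168 lower, 1007 passed with the animal as a random block, 58 with the spike-in signal as a covariate, 11 with the day 14 arrays alone, and 0 within batch 4 alone by limma, with 1537 at an unadjusted p under 0.05. Without FR104.Siro.D14 replicates 26, 29 and 28 the count was 224, 47 and 711, and without FR104.Siro.F replicates 27, 26 and 29 it was 28, 46 and 999.

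For FR104.F against FR104.D14 and Tac.Mtx.F against Tac.Mtx.D14 limma called 0 genes, with 340 and 516 at an unadjusted p under 0.05 (n = 3 against 3 each). In Tac.Mtx 1 gene passed with the animal as a random block, and 1, 2 and 1 passed without Tac.Mtx.D14 replicates 21 and 20 and Tac.Mtx.F replicate 21. No type I interferon response gene of 17 passed in FR104, over all genes or adjusted over the list alone, although the list moved down (median -0.50, adjusted p 3.12e-06, 0.272 with an estimated correlation). Up in FR104 moved cholesterol synthesis (1 of 11 adjusted over the list alone; median 0.25, adjusted p 5.24e-05, 0.156 with an estimated correlation), and with 0 called either way cell cycle (0.33, 0.0026, 0.598), immediate early stress response (0.38, 0.0269, 0.433) and Th17 and Tc17 genes (0.28, 0.0273, 0.403). Without FR104.F replicate 22 the last 3 were at -0.03, 0.19 and -0.04 and missed the threshold. In Tac.Mtx the 16 cytotoxic effector genes moved up, with 0 called either way adjusted over the list alone (median 0.73, adjusted p 0.000392, 0.395 with an estimated correlation; 0.42, adjusted p 0.172, without Tac.Mtx.F replicate 19). The NK cell list did not pass (0 of 9 called, also adjusted over the list alone; median 0.34, adjusted p 0.433, 0.773 with an estimated correlation). Monocyte and erythroid markers moved down there (0 of 12, and 0 of 6 with 1 higher adjusted over the list alone; median -0.28 and -0.65, adjusted p 0.0425 and 0.0369, with an estimated correlation 0.616 and 0.589). Without Tac.Mtx.D14 replicate 21 the erythroid list turned to 0.67. Immediate early stress response (4 of 7 higher and 1 lower adjusted over the list alone; 0.89, 0.00155, 0.302) and Th17 and Tc17 genes (1 of 14; 0.24, 0.00402, 0.302) moved up, with FOS at 4.29 ± 1.32 (adjusted p 0.819), and naive T cell genes down (2 of 10; -0.42, 4.59e-05, 0.232). Glycolysis, cholesterol synthesis and apoptosis lists passed as well, with adjusted p of 0.0235, 0.0407 and 0.0432. Of the 9 lists only the naive one passed with each array left out in turn. The change over time under FR104.Siro differed from that under Tac.Mtx for 1 gene, PTCHD1 (1.37 against -0.98, difference 2.36 ± 0.44, adjusted p 0.0164), and from that under FR104 for 0 genes by limma, with 315 at an unadjusted p under 0.05. With the animal as a random block the counts were again 1 and 0 by limma (1527 and 501 at an unadjusted p under 0.05). PTCHD1 missed the threshold without 7 of the 14 arrays. By lists the change differed from FR104 at the preset correlation alone. Type I interferon response (median difference 0.845, adjusted p 2.32e-08, 0.0884 with an estimated correlation) and cell cycle genes (0.55, 3.76e-06, 0.566) were higher. So were inhibitory receptors (0.37, 0.000907, 0.0741) and regulatory T cell genes (0.31, 0.00512, 0.0741), and erythroid markers were lower (-0.83, 0.0119, 0.642). A sixth, cytotoxic effector genes (0.35, 0.044, 0.751), missed the threshold without 7 of the 14 arrays, the regulatory list without 1 and the erythroid list without 2 (-0.14, adjusted p 0.817, without FR104.F replicate 24). With 1 array left out the first 4 ran from 0.59 to 1.13, 0.33 to 0.85, 0.23 to 0.49 and 0.19 to 0.40. The spike-in signal and later days of FR104.Siro.D14 were not tested here. From Tac.Mtx cell cycle (0.74, 1.72e-05, 0.596), monocyte (0.82, 0.00578, 0.627), regulatory T cell (0.43, 0.0176, 0.143) and naive genes (0.20, 0.0207, 0.618) differed, and missed the threshold without 1, 1, 1 and 5 arrays (cell cycle at 0.19 without Tac.Mtx.F replicate 19).

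The remaining groups were each set against the 34 healthy controls. In Auto.D36, IFI27 rose by 3.63 ± 0.59, CX3CR1 by 3.40 ± 0.46, and MB by 2.73 ± 0.45, and SOX4, MAML3 and RASGRF2 fell by 3.68 ± 0.96, 2.68 ± 0.43 and 2.39 ± 0.42 (n = 3). Cell cycle genes rose in 13 of 18 cases, 13 adjusted over the list alone (median 1.40, adjusted p 1.1e-11, 0.236 with an estimated correlation). Of 1976 genes, 926 were higher and 1050 lower, 1095 passed within batch 4 alone, and 1185 and 1089 without Auto.D36 replicates 201 and 200. The actin 3' minus 5' signal of the group averaged -0.33, against 1.305 in healthy controls, and with it as a covariate 646 genes passed, SOX4 not among them. In Siro.F, SERPINE2 rose by 3.38 ± 0.45, S100A9 by 3.05 ± 0.80, CTLA4 by 1.54 ± 0.32 and CCNB2 by 2.40 ± 0.39, and AUTS2, SOX4 and METTL14 fell by 2.47 ± 0.35, 2.43 ± 0.77 and 2.40 ± 0.72 (n = 4). Inhibitory receptors rose in 6 of 12 cases, 6 adjusted over the list alone (median 0.67, adjusted p 2.47e-05, 0.075 with an estimated correlation), led by LAG3 (2.69 ± 0.30). Of 1725 genes, 976 were higher and 749 lower, 289 passed in batch 1 alone and 1279 in batch 2 alone, and 879 without Siro.F replicate 18.

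In the 3 Tac.Mtx groups type I interferon genes rose over healthy controls. At D14, CMPK2 rose by 2.16 ± 0.35, IFIT1B by 2.71 ± 0.50, and S100A9 by 3.68 ± 0.90. BTG2, ANKRD50 and CAMK4 fell by 1.27 ± 0.28, 1.23 ± 0.34 and 0.66 ± 0.17 (n = 3). AHSP, the alpha globin chaperone of red cell precursors, rose by 2.07 ± 0.39, with 5 of 6 erythroid markers higher and, adjusted over the list alone, 5 higher and 1 lower (median 1.59, adjusted p 6.29e-06, 0.248 with an estimated correlation). Without replicate 21 AHSP was at 0.53 and the list at a median of 0.20, with adjusted p of 0.669 and 0.725. Type I interferon response genes rose in 7 of 17 cases, with 11 higher and 2 lower adjusted over the list alone (median 0.96, adjusted p 5.1e-09, 0.156 with an estimated correlation), and monocyte and myeloid markers in 2 of 12, 4 adjusted over the list alone (median 0.60, adjusted p 0.00092, 0.392 with an estimated correlation). At D30, IFI27 rose by 3.36 ± 0.63, ISG15 by 2.73 ± 0.39, and ZZEF1 by 3.30 ± 0.99. SELENOP, SLC16A10 and KANSL1L fell by 2.93 ± 0.76, 2.28 ± 0.61 and 2.23 ± 0.39 (n = 2). Of these ISG15 alone passed with either array left out. Type I interferon response genes rose in 11 of 17 cases and 14 adjusted over the list alone (median 1.74, adjusted p 2.44e-15, 0.0523 with an estimated correlation). At F, FOS rose by 3.85 ± 1.03, S100A9 by 3.86 ± 0.90, CMPK2 by 2.23 ± 0.35 and IL17A by 0.68 ± 0.16, and SOX4, SELENOP and ACKR1 fell by 2.58 ± 0.87, 2.20 ± 0.64 and 2.07 ± 0.37 (n = 3), and type I interferon response genes rose in 10 of 17 cases, 12 adjusted over the list alone (median 1.00, adjusted p 1.3e-07, 0.215 with an estimated correlation). The counts were 173 at D14 (165 higher), 408 at D30 (336 higher) and 1665 at F (1262 higher), and 203, 426 and 1551 within batch 3 alone. They were 39 and 59 without Tac.Mtx.D14 replicates 21 and 20, 15 and 72 without Tac.Mtx.D30 replicates 19 and 20, and 801 and 398 without Tac.Mtx.F replicates 21 and 20.

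In Bela.F against healthy controls, S100A8 and S100A9 rose by 6.07 ± 0.86 and 6.38 ± 0.90, CCL23 by 4.96 ± 0.83, LAG3 by 3.71 ± 0.34, CCNB2 by 3.37 ± 0.44 and GZMB by 1.41 ± 0.45. Other markers of myeloid cells rose with them: VCAN by 3.21 ± 0.78, FCN1 by 2.81 ± 0.69, and the granule proteins CAMP and LCN2 by 2.37 ± 0.53 and 2.27 ± 0.36. Of 8 neutrophil and granule markers 4 rose, 4 adjusted over the list alone (median 0.70, adjusted p 0.0409, 0.485 with an estimated correlation; adjusted p 0.0595 and 0.0928 without replicates 57 and 46). Of 12 monocyte and myeloid markers 4 rose and 1 fell, and the list did not pass (adjusted p 0.0626). CAVIN2, MAMDC2 and JAKMIP2 fell by 2.35 ± 0.68, 2.26 ± 0.38 and 2.16 ± 0.53 (n = 3). Cell cycle genes rose in 17 of 18 cases, 17 adjusted over the list alone (median 1.91, adjusted p 7.1e-21, 0.122 with an estimated correlation). Of 2082 genes, 1462 were higher and 620 lower, 1937 passed within batch 3 alone, and 818 and 1196 without Bela.F replicates 47 and 46. In the Bela.Siro groups PCDH8 rose by 3.99 ± 0.24 at D30 (n = 3) and 4.46 ± 0.29 at F (n = 2), IL17A by 1.93 ± 0.19 at F, and S100A9 by 4.53 ± 0.90, 4.43 ± 0.90 and 5.32 ± 1.06 at D14 (n = 3), D30 and F. VCAN rose by 2.95 ± 0.78 at D14. Monocyte and myeloid markers rose in 4, 4 and 3 of 12 cases at D14, D30 and F, 5, 4 and 5 adjusted over the list alone (adjusted p 0.00202, 0.0124 and 7.34e-05, with an estimated correlation 0.418, 0.517 and 0.302). Each missed the threshold without 1 array: replicate 38 at D14 (adjusted p 0.0587) and replicate 42 at D30 (0.0658) and F (0.384, median 0.075 in place of 1.10). FAM110C, PTGDR and SMAD7 fell by 2.25 ± 0.62, 2.11 ± 0.50 and 1.96 ± 0.37 at D14 and by 2.14 ± 0.62, 1.97 ± 0.50 and 1.88 ± 0.37 at D30. At F, PTGDR, FGFBP2 and ST8SIA1 fell by 2.70 ± 0.59, 2.64 ± 0.76 and 1.82 ± 0.43. All genes named at F but IL17A and PCDH8 missed the threshold without 1 of its 2 arrays. Th17 and Tc17 genes rose at F in 3 of 14 cases and 7 adjusted over the list alone (median 0.73, adjusted p 5.68e-11, 0.00804 with an estimated correlation). The counts were 297 (235 higher), 847 (499 higher) and 335 (221 higher), and 267, 537 and 391 within batch 3 alone. They were 29 and 193 without Bela.Siro.D14 replicates 42 and 49, 1484, 306 and 234 without Bela.Siro.D30 replicates 38, 42 and 49, and 189 and 35 without Bela.Siro.F replicates 38 and 42.

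For FR104 against healthy controls, S100A9 rose by 4.72 ± 0.99 at D14 and 3.95 ± 0.99 at F, IFI27 by 3.99 ± 0.59 at D14, ZBED2 by 4.10 ± 0.62 at F, and MKI67 by 1.80 ± 0.37 and 2.09 ± 0.37 (n = 3 each). FOS, SELENOP and DUSP1 fell by 3.75 ± 1.14, 3.56 ± 0.71 and 2.63 ± 0.67 at D14, and KLRF1, TPD52 and SAMD3 by 3.16 ± 0.86, 2.41 ± 0.52 and 2.39 ± 0.56 at F. Cell cycle genes rose in 13 of 18 cases at D14 and 15 adjusted over the list alone (median 1.20, adjusted p 4.47e-15, 0.156 with an estimated correlation). At F they rose in 15 of 18, with 16 higher and 1 lower adjusted over the list alone (median 1.46, adjusted p 7.06e-19, 0.156 with an estimated correlation). The counts were 636 (305 higher) and 1259 (636 higher), 313 and 571 within batch 4 alone, 301 and 136 without FR104.D14 replicates 22 and 23, and 246 and 718 without FR104.F replicates 22 and 23. Neutrophil and granule markers rose in 2 and 3 of 8 cases, 3 and 3 adjusted over the list alone (adjusted p 0.0101 and 0.0258, 0.377 and 0.439 with an estimated correlation; adjusted p 0.061 and 0.637 without FR104.D14 replicate 23 and FR104.F replicate 24). The actin 3' minus 5' signal was 0.02 to 0.37 at D14 and 0.095 to 0.425 at F, below every healthy control, and with it as a covariate 305 and 729 genes passed. Under FR104.Siro, CCL23 rose by 3.98 ± 0.83 at D14 and 4.33 ± 0.83 at F, S100A9 by 3.35 ± 0.90 and 4.57 ± 0.90, SOCS2 by 3.08 ± 0.57 at D14 and IL26 by 2.06 ± 0.39 at F (n = 4 each). FOS, NR4A2 and G6PC2 fell by 3.18 ± 1.04, 2.86 ± 0.71 and 2.49 ± 0.48 at D14, and GZMH, METTL14 and SORD by 3.39 ± 0.62, 3.14 ± 0.82 and 2.63 ± 0.50 at F. Cytotoxic effector genes fell in 5 of 16 cases at D14 and 10 adjusted over the list alone (median -1.18, adjusted p 4.99e-05, 0.342 with an estimated correlation). At F they fell in 7 of 16 and 10 adjusted over the list alone (median -1.12, adjusted p 4.61e-05, 0.341 with an estimated correlation). Neutrophil and granule markers rose at F in 3 of 8 and 5 adjusted over the list alone (median 0.95, adjusted p 0.000154, 0.23 with an estimated correlation). The counts were 2149 (1006 higher, 48 by at least 2-fold) and 1187 (343 higher), 714 and 426 within batch 4 alone, 1236 without FR104.Siro.D14 replicate 29, and 753 and 666 without FR104.Siro.F replicates 27 and 28. At D14 all 4 arrays had a spike-in signal above every healthy control, and 168 genes passed with that signal as a covariate and 477 with the day 14 arrays alone.

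**Figure D3:**
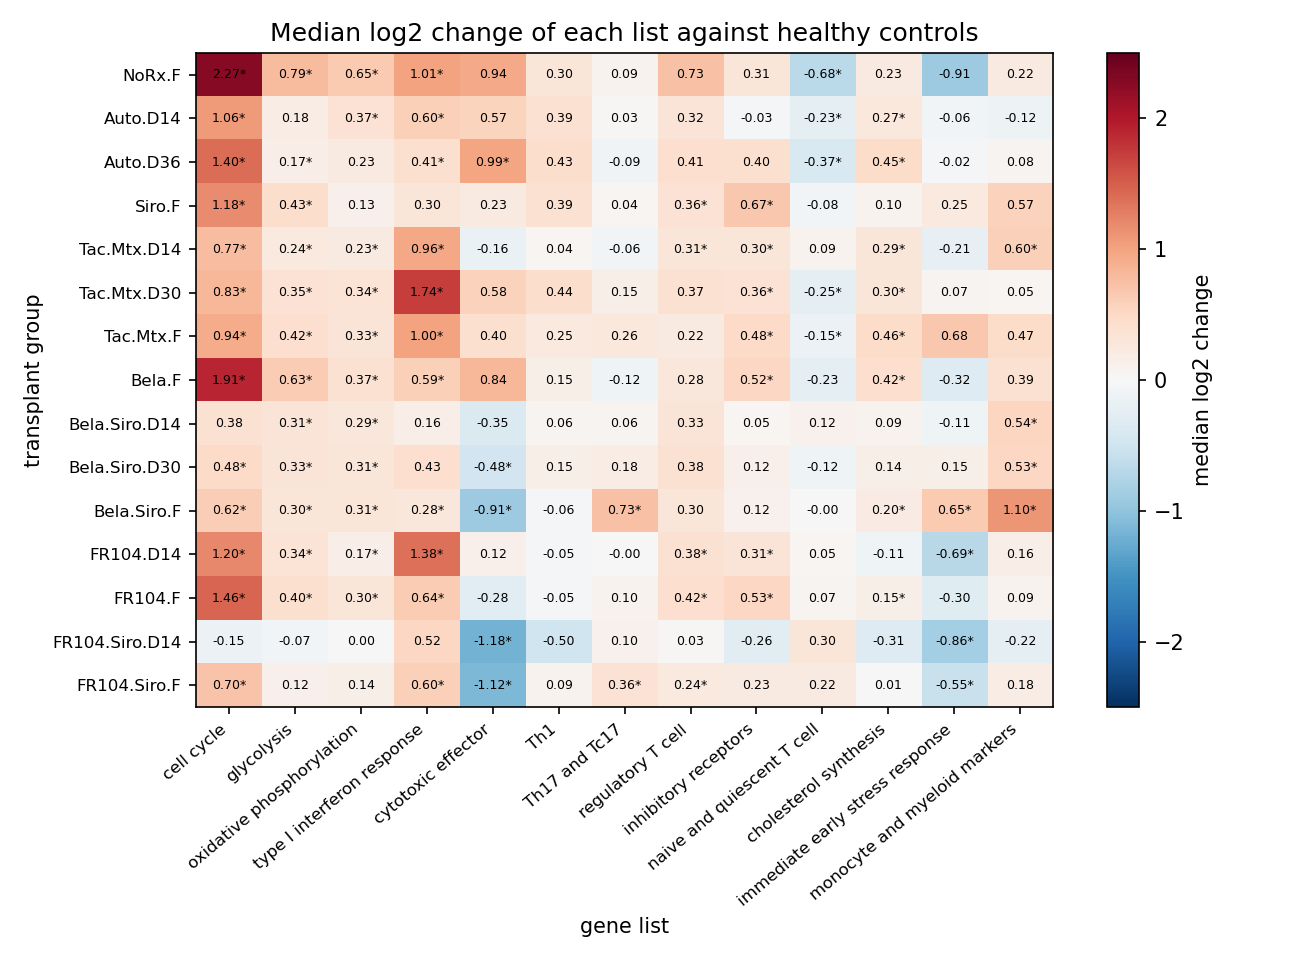
Median log2 change of 13 gene lists (horizontal axis) in each transplant group (vertical axis) against healthy controls, with the value in each cell and a star for an adjusted p under 0.05 with the preset correlation. Cell cycle medians ran from -0.15 in FR104.Siro.D14 to 2.27 in NoRx.F.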

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

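The S100A8 test was chosen before its result was seen. The tests of differences between effects were added after the data were seen. The counts of other splits, the tests of the spike-in signal and of the later days in FR104.Siro.D14, the S100A8 count over groups and the tests of CD8 T cells and NK cells were chosen after the results were seen.

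In 5 of 112 list scores of groups of 4 arrays, 1 array stood apart from the rest of its group by more than a critical gap, which chance gives in about 1 in 20. The B cell marker score of NoRx.F replicate 51 was -0.003 (others 0.094 to 0.108), the T cell activation and MHC class II score of Siro.F replicate 18 0.91 (0.116 to 0.191), the type I interferon score of FR104.Siro.D14 replicate 26 1.152 (0.092 to 0.158), the oxidative phosphorylation score of FR104.Siro.D14 replicate 27 0.212 (-0.006 to 0.001) and the T cell identity score of FR104.Siro.F replicate 26 -0.152 (0.178 to 0.197).

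The effect of adding Siro differed between FR104 and Bela in a test of the difference: IL17A by -2.199 ± 0.298, IL22 by -1.323 ± 0.28, CRYBB1 by 1.474 ± 0.282, and the Th17 and Tc17 list by a mean of -0.684 (median -0.495, adjusted p 6.54e-08, 0.0192 with an estimated correlation). With each of the 12 arrays left out in turn, IL17A ran from -2.496 to -1.755 and the list median from -0.673 to -0.249. CRYBB1 and IL22 missed the threshold without 5 and 8, and IL22 with the animal as a random block (adjusted p 0.0713). Other lists differed at the preset correlation alone. The change over time differed between FR104.Siro and Tac.Mtx for PTCHD1, by 2.356 ± 0.444, which missed the threshold without 7 of 14 arrays. Bela.Siro.F has 2 arrays, and without either its spread was taken from other groups, so such a fit is little check. Of 16975 probe sets without a gene name here, 3329 changed in NoRx.F against healthy controls (1243 higher, 2086 lower), 19.6% beside 35.4% of named genes.

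Many small changes marked FR104.Siro.D14 against healthy controls: 2149 genes with a median size of 0.456 and a median SE of 0.133. The spike-in signal of the group was 1.053 above that of the controls, and the slope of the other arrays gave a median of 0.35 of the observed change (0.306 to 0.383 without 1 other array of high signal). With the signal as a covariate the size was 0.312, the SE 0.158, and 168 genes passed, 149 of them among the 2149, with 99.7% of the 2149 in the same direction: the call ended for most because the size fell and the SE rose. Less labelled RNA could thus account for part of the pattern, and the rest cannot be told apart from the prophylaxis, since all 4 arrays of the group have a high signal. The day 14 arrays alone gave a median of 0.924 of the change, but the genes were picked with these arrays, so this says little on the later days. Alone they called 477 genes, 436 among the 2149, without days 22 and 34. An effect of FR104.Siro itself was not tested apart from this and stays open.

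S100A8 and S100A9 were higher in NoRx.F than in healthy controls. Over the 81 arrays, within groups, their mean went with that of 10 other monocyte and myeloid markers (r 0.742, rank correlation 0.717, each with a permutation p of 1e-05, the smallest that 100000 permutations can give; r 0.718 without the 2 farthest arrays). In batches 1 to 4 r was 0.848, 0.558, 0.798 and 0.76, in controls 0.894 and in transplant arrays 0.67. In NoRx.F 3 of the 10 rose, FCN1, VCAN and CLEC7A, by 2.234, 1.988 and 0.304, while LYZ (1.875 ± 0.8), CD14 (-0.12 ± 0.303) and CSF1R (-0.029 ± 0.245) did not pass, and the median was 0.052. The median of 8 neutrophil markers was 0.197. In Bela.F 4 of the 8 rose (median 0.7), which was not tested further. Monocytes that escaped the CD3 sort, which would remove them, may be a source of the 2 transcripts, as a hypothesis found on these data, but CD14 and CSF1R give no sign of them in NoRx.F. Both transcripts also rose in 11 of 12 prophylaxed groups, some of the same animals (S100A8 by 2.835 to 6.072). In Auto.D14 and Auto.D36 neither passed. Induction within T cells was not tested and stays open.

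Cytotoxic effector genes were lower in FR104.Siro.F than in NoRx.F, by a mean of 2.021 ± 0.44. CD8A and CD8B were lower by 0.91 ± 0.296 and the NK cell markers by 0.28 ± 0.507. The change of the CD8 genes minus that of the cytotoxic genes was 1.11 ± 0.477, and that of the NK cell markers 1.741 ± 0.295. This argues against a smaller share of all CD8 T or NK cells as the whole cause. In FR104.F against NoRx.F, where the cytotoxic genes were lower by 1.123 ± 0.464, the same differences were 0.558 ± 0.502, within 2 SE, and 1.352 ± 0.311, so for that group a smaller share of CD8 T cells stays open. FR104.Siro may lower the effector program or the share of effector cells, both untested. No batch is shared, so a batch difference stays open.

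Chance is less likely where few array splits into groups of the same sizes, whatever the batch, gave as many genes. Against healthy controls 100 splits were drawn, and the real split was the 1 with as many in NoRx.F (4181 genes; highest other 2697), Auto.D14 (519; 95), Auto.D36 (1976; 1041), Siro.F (1725; 430), Tac.Mtx.D14 (173; 22), Tac.Mtx.F (1665; 1), Bela.F (2082; 3), Bela.Siro.D30 (847; 87), FR104.D14 (636; 317), FR104.F (1259; 63), FR104.Siro.D14 (2149; 5) and FR104.Siro.F (1187; 6). In Bela.Siro.D14 2 of 100 gave as many (297; 510), the other with control arrays of batches 1 and 3. Of 35 splits, 1 gave as many in Siro.F (1425; 502) and FR104.Siro.F (2319; 649) against NoRx.F and in FR104.Siro.D14 against Auto.D14 (1801; 810).

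Chance could not be excluded in 6 comparisons with 35 splits. As many genes came from 2 splits in NoRx.F against Auto.D14 (393; 658), Tac.Mtx.F (820; 955), Bela.F (220; 430) and FR104.F (906; 927) against NoRx.F, 2 in FR104.Siro.F against FR104.Siro.D14 (366; 690) and 13 in FR104.Siro.F against FR104.F (1; 8). In the first 4 the other split followed batch: it set the 3 NoRx.F arrays of batch 1 against the rest with NoRx.F replicate 53 of batch 2. No batch holds both groups, and with the animal as a random block the counts were 696, 863, 231 and 1029. The arrays of FR104.Siro.F and FR104.Siro.D14 are pairs of 4 animals, and there the other split kept replicate 28 of both days on 1 side. Of the 8 splits that part every pair, a test added after the data were seen and too few for a share under 0.05, 1 gave as many (366; highest other 0), and 1 with the animal as a random block (1007; 121).

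Groups of 3 against 3 make 10 splits, too few for a share under 0.05. As many genes came from 2 in FR104.F against Bela.F (4; highest other 7), 1 in FR104.D14 (29; 0), 2 in Tac.Mtx.D14 (2; 4) and 1 in Bela.Siro.D14 (11; 2) against Auto.D14, and 1 in Auto.D36 against Auto.D14 (115; 1; among the 4 splits that part every pair also 1). In FR104.F against FR104.D14 and Tac.Mtx.F against Tac.Mtx.D14 limma called 0 genes (340 and 516 at an unadjusted p under 0.05), so all 10 splits give as many by construction and test nothing.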

How the results depend on the processing

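The tests with the spike-in and actin signals and without the arrays where the former was high and those of differences between effects were chosen after the data were seen, and the others before. Counts that moved by more than 1.5 times are given, by setting; the cause of a move was not tested unless named. Without a batch term the counts were 1471 in Auto.D14, 3029 in Auto.D36, 333 in Tac.Mtx.D14, 724 in Tac.Mtx.D30, 602 in Bela.Siro.D14, 1296 in Bela.Siro.D30, 567 in Bela.Siro.F, 1516 in FR104.D14, 2237 in FR104.F, 4211 in FR104.Siro.D14 and 2342 in FR104.Siro.F against controls. Against NoRx.F there were 1793 in Tac.Mtx.F, 711 in Bela.F, 1629 in Bela.Siro.F, 2181 in FR104.F and 3749 in FR104.Siro.F. Against Auto.D14 there were 1376 in NoRx.F, 61 in FR104.D14, 98 in Tac.Mtx.D14 and 198 in Bela.Siro.D14. FR104.F against Bela.F gave 41. With the animal as a random block they were 798 in Auto.D14 against controls. Against Auto.D14 there were 696 in NoRx.F, 7 in Tac.Mtx.D14, 19 in Bela.Siro.D14 and 339 in Auto.D36. There were 1007 in FR104.Siro.F against FR104.Siro.D14 and 1 in Tac.Mtx.F against Tac.Mtx.D14. With the mean of the probe sets of a gene they were 83 in Bela.F against NoRx.F, 4 in FR104.Siro.F against FR104.F and 616 in FR104.Siro.F against FR104.Siro.D14. Against Auto.D14 they were 230 in NoRx.F, 4 in Bela.Siro.D14, 363 in Auto.D36 and 0 in Tac.Mtx.D14 (limma, 991 at an unadjusted p under 0.05). With only the groups compared and the healthy controls they were 351 in Tac.Mtx.D14, 625 in Tac.Mtx.D30, 508 in Bela.Siro.D14 and 594 in Bela.Siro.F against controls. Between groups there were 13 in FR104.Siro.F against FR104.F, 142 in Bela.Siro.F and 7 in FR104.F against Bela.F and 3 in Tac.Mtx.F against Tac.Mtx.D14. Against Auto.D14 there were 73 in FR104.D14, 10 in Tac.Mtx.D14 and 27 in Bela.Siro.D14. Without the filter on dim probe sets they were 6 in Bela.Siro.D14 against Auto.D14 and 563 in FR104.Siro.F against FR104.Siro.D14. After renewed quantile normalization they were 2 in FR104.Siro.F against FR104.F, 58 in FR104.D14 against Auto.D14 and 582 in FR104.Siro.F against FR104.Siro.D14. With only the day 14 arrays of FR104.Siro.D14 they were 477 in FR104.Siro.D14 against controls. Between groups there were 729 in FR104.Siro.D14 against Auto.D14 and 11 in FR104.Siro.F against FR104.Siro.D14. With the spike-in signal as a covariate they were 168 in FR104.Siro.D14 against controls. Between groups there were 2 in FR104.Siro.F against FR104.F and 58 in FR104.Siro.F against FR104.Siro.D14. Against Auto.D14 there were 1188 in FR104.Siro.D14, 2 in Bela.Siro.D14, 27 in Auto.D36 and 0 in Tac.Mtx.D14 (limma, 780 at an unadjusted p under 0.05). With the actin 3' minus 5' signal as a covariate they were 646 in Auto.D36, 305 in FR104.D14 and 729 in FR104.F against controls. Among groups they were 1 in FR104.F against Bela.F and 1 in Auto.D36 against Auto.D14. Without the 8 arrays of high spike-in signal they were 20 in Auto.D14, 221 in Bela.Siro.F and 153 in FR104.D14 against controls. Between groups there were 3 in FR104.Siro.F against FR104.F and 7 in Auto.D36 against Auto.D14. Limma called 0 in FR104.D14, Tac.Mtx.D14 and Bela.Siro.D14 against Auto.D14, with 677, 641 and 1029 at an unadjusted p under 0.05. In batch 2 there is 1 NoRx.F array, so its spread is that of the other arrays and those counts are no check of the group. In batch 1 the counts were 289 in Siro.F against controls. In batch 2 the counts were 833 in NoRx.F against controls and 2 in Siro.F against NoRx.F. In batch 3 the counts were 537 in Bela.Siro.D30 against controls and 7 in Bela.Siro.F against Bela.F. Batch 4 gave 90 in Auto.D14, 1095 in Auto.D36, 313 in FR104.D14, 571 in FR104.F, 714 in FR104.Siro.D14 and 426 in FR104.Siro.F against controls. Against Auto.D14 there were 17 in FR104.D14 and 656 in FR104.Siro.D14. Limma called 0 in FR104.Siro.F against FR104.F, Auto.D36 against Auto.D14 and FR104.Siro.F against FR104.Siro.D14, with 776, 898 and 1537 at an unadjusted p under 0.05. With an estimated correlation 2 of 213 gene list shifts passed. Leaving out each transplant array in turn gave lowest and highest counts, and the report names the arrays that moved a count by more than 1.5 times. Against controls they were NoRx.F 3590 to 3926, Auto.D14 21 to 566, Auto.D36 1089 to 1638, Siro.F 879 to 1487, Tac.Mtx.D14 39 to 235, Tac.Mtx.D30 15 to 72, Tac.Mtx.F 398 to 1357, Bela.F 818 to 2182, Bela.Siro.D14 29 to 237, Bela.Siro.D30 234 to 1484, Bela.Siro.F 35 to 189, FR104.D14 136 to 618, FR104.F 246 to 1107, FR104.Siro.D14 1236 to 2030 and FR104.Siro.F 666 to 1235. For the final samples they were NoRx.F against Auto.D14 175 to 790, Siro.F against NoRx.F 845 to 1681, Tac.Mtx.F against NoRx.F 432 to 1180, Bela.F against NoRx.F 86 to 454, Bela.Siro.F against NoRx.F 316 to 1140, FR104.F against NoRx.F 294 to 1296, FR104.Siro.F against NoRx.F 1862 to 2487, FR104.Siro.F against FR104.F 1 to 3, Bela.Siro.F against Bela.F 14 to 179 and FR104.F against Bela.F 0 to 16. Against Auto.D14 they were FR104.D14 0 to 33, FR104.Siro.D14 1071 to 1694, Tac.Mtx.D14 0 to 26, Bela.Siro.D14 0 to 35 and Auto.D36 7 to 565. Over time they were FR104.F against FR104.D14 0, FR104.Siro.F against FR104.Siro.D14 28 to 999 and Tac.Mtx.F against Tac.Mtx.D14 0 to 2. For the differences between effects (Siro added to FR104 against Bela, and change over time under FR104.Siro against FR104 and Tac.Mtx) they were 1 to 12, 0 to 1 and 0 to 2, and 3 (IL22, adjusted p 0.0713, not among them), 0 (limma; 501 at an unadjusted p under 0.05) and 1 with the animal as a random block. The direction in the list test, which sets the members against the other genes, or the sign (GZMB, CD8B) turned in these, with medians for lists and in brackets the lowest and highest: CD8B in Bela.Siro.F against Bela.F from -0.722 to 0.019 without Bela.Siro.F replicate 38 (-1.462 to 0.019), the cell cycle list in FR104.F against FR104.D14 from 0.331 to -0.034 without FR104.F replicate 22 (-0.034 to 0.533) and the Th17 and Tc17 list in FR104.F against FR104.D14 from 0.278 to -0.042 without FR104.F replicate 22 (-0.042 to 0.399). It turned too in GZMB in FR104.Siro.F against FR104.F from -0.635 to 0.024 without FR104.F replicate 24 (-1.699 to 0.024), the erythroid markers list in Tac.Mtx.D14 against Auto.D14 from 1.446 to 0.033 without Tac.Mtx.D14 replicate 21 (0.033 to 2.134), the erythroid markers list in Tac.Mtx.F against Tac.Mtx.D14 from -0.652 to 0.669 without Tac.Mtx.D14 replicate 21 (-1.403 to 0.669) and the cell cycle list in Tac.Mtx.D14 against Auto.D14 from -0.28 to 0.096 without Tac.Mtx.D14 replicate 19 (-0.539 to 0.096). Of the named gene values, these missed the threshold that they had passed: 31 with the mean of the probe sets, 10 without the filter, 3 with the block, 23 with the spike-in covariate, 16 with the actin covariate. With 1 array left out, 299 values of named genes missed the threshold and 1348 kept their side of it, and for lists these were 189 and 1006. Signal over background limits dim genes, whose changes are compressed, and genes with no probe set named here are not covered.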

Other observations

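No batch holds both partners of Siro, FR104 and Bela, so whether the partner, the batch or the animals set the difference of IL17A (-0.087 and 2.112) was not tested.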
